A study of Sus scrofa with 13 samples.

How the data were processed

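Gene expression in fetal pig longissimus dorsi, the long muscle of the back, was measured on dual-colour arrays of 20400 oligonucleotides (70-mers), per the labels. RNA of 3 fetuses of a litter was pooled, and each of the 14 pools came from another gilt. The pools fell into 4 groups: 4 Piau pools at day 40 of gestation, 4 Piau pools at day 70, 3 Yorkshire x Landrace crossbred pools at day 40 and 3 crossbred pools at day 70. The 13 arrays formed 3 closed loops of 4 arrays, in which each pool was hybridised once with Cy3 and once with Cy5, and 1 further array compared Piau pools 515 and 386. Per the labels' protocols, Piau RNA was prepared with a column kit and on-column DNase digestion, and crossbred RNA with a phenol-based reagent from a larger piece of tissue. All RNA was then amplified from an oligo(dT) primer before dye coupling.

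The authors deposited 1 normalised log ratio per probe and array, taken here as log2 ratios, and the series design text names LOESS normalisation of the fluorescence intensities followed by a mixed model. The base of the logarithm is not given in the sources used here: base 10 would exceed the range of a scanner, and a natural logarithm was not excluded, under which every printed value would be a natural log of the same size. Scanner, background correction and filters are not given in the sources used here, and single-channel intensities and control-spot labels were not used here. Signal over background was therefore unknown, and the number of arrays limits the precision. The table held 20736 probes on 13 arrays with no missing value, and the array medians lay between -0.01 and 0.00.

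Which dye was the numerator is not given either. Arrays of the same kind and the same dye orientation correlated at 0.54 to 0.73 over all probes, and those of opposite orientation at -0.34 to 0.08. With the mean of the loop arrays removed as a dye effect, the ranges were 0.37 to 0.61 and -0.75 to -0.39. A fit with the same dye over the other on all arrays left a median residual SD of 0.180, against 0.210 when arrays were taken as turned to a fixed order of groups. All arrays were therefore treated as running the same way. The overall sign was to be read from lists of proliferation, fast fibre and glycolysis genes, but these had 0 named probes, so it stayed open. Values are printed with the sign they have if the ratios are Cy5 over Cy3, and every sign turns if they are the inverse.

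Gene names came from the platform annotation, which gave 1 symbol to 178 probes (175 genes) and none to 20558 probes. No probe had several symbols. All 178 Entrez identifiers were found in the RefSeq gene table of the assembly Sscrofa11.1, used for names alone. ASIP had 4 probes, and none of them passed the threshold in any comparison. No coordinates are given because no genome build belongs to the probes.

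Each comparison came from 1 generalised least squares fit to all 13 arrays, with the 4 groups as fixed effects, 1 dye intercept per probe and the litter pool as a random effect. The pool variance was 0.119 times the array variance, estimated over all probes by restricted maximum likelihood. Two-sided tests used limma 3.58.1 in R 4.3.3 with empirical Bayes moderation (9 residual and 3.08 prior degrees of freedom) and Benjamini-Hochberg adjustment over 20736 probes, with a threshold of 0.05. Errors are standard errors of that fit unless an SD is named. The comparisons were day 70 minus day 40 in each breed, Piau minus crossbred at each age, the difference of the age changes (the interaction), and the averages over breeds or ages. The design, the 23 gene lists, the wording of the rule for named genes and the alternatives other than those named below as added were fixed before the data were examined.

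The procedure was tested on simulated data over 20736 probes, drawn once per comparison from the fitted model itself. Errors were normal, with 1 pool variance ratio for all probes, and far fewer probes were changed than passed in the data. The simulation therefore cannot show whether these assumptions hold, and differences between the comparisons include the chance of the draw. For the age change in Piau it recovered 81 of 100 probes changed by 0.5 and 98 of 100 changed by 1, with 8 false among 187 calls. In crossbred fetuses these were 62 and 93, with 12 false among 167. For the breed difference at day 40 they were 52 and 94, with 6 false among 152, and at day 70 they were 70 and 97, with 7 false among 174.

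The rule for named genes took, among probes with 1 symbol, those past the threshold with the same sign on every array that hybridised the compared groups directly, up to 12 per side. For the interaction it took the 5 with the smallest p if none passed. The sign was read from the deposited ratios without removing the dye effect, a reading chosen after both versions had been seen. It left out PAQR8, LMCD1 and OCA2 for the age change in Piau and MAOA for the breed difference at day 70, which are given as such. With the dye effect removed, each of these kept 1 sign. Values of single arrays are printed with the dye effect removed. Of the 23 gene lists, 12 had a named member, 16 members in all and at most 3 in a list. The planned set tests (camera with preset and with estimated correlation, and fry) had too few members to be informative and were not run.

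Alternatives covered the dependence between arrays, the direct arrays alone, the dye term, centring and scaling, moderation, thresholds, 1 value per named gene, and leaving out the extra array or each loop. Removing the median of each of 48 print blocks, taken as 432 consecutive probe numbers, and leaving out each array in turn were added after the data were seen. The loops, which tie 1 pool of each group together, entered as a block in the alternative with 1 level per pool. For named genes, the alternatives of dependence, dye term, scaling and moderation were also added after the data were seen.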

Results

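Transcript levels in the longissimus dorsi of pig fetuses were compared between days 40 and 70 of gestation and between Piau, a local Brazilian breed, and Yorkshire x Landrace crossbreds. Of the 13 arrays, 4 compared the ages in Piau, 3 compared the ages in crossbreds, 3 compared the breeds at day 40 and 3 compared them at day 70. The SD of the log ratios of an array ran from 0.317 to 0.442. Only 178 of the 20736 probes carried a gene name, so most of the changed transcripts are described as counts. The dye in the numerator was not given in the sources used here. A positive value stands for more RNA at day 70, or more in Piau, if the ratios are Cy5 over Cy3, and for less if they are the inverse. Sizes, sides relative to other genes and tests do not depend on this choice.

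The first question was how the muscle transcriptome differed between the ages in Piau. The antimicrobial cathelicidin PR39 (probe 3414) had the largest value among the named genes past the threshold, 1.80 ± 0.19 (SE, adjusted p = 0.000121). Its 4 direct arrays ran from 0.96 to 2.28. CAV1 (probe 13782), the main coat protein of caveolae, lay on the same side at 0.90 ± 0.13 (adjusted p = 0.00137), with 4 arrays between 0.64 and 1.16. S100A11 (probe 11187), a calcium-binding protein, lay on the opposite side at -0.74 ± 0.09 (adjusted p = 0.0004), and its arrays ran from -0.85 to -0.49.

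ITM2A, a membrane protein, was at 0.40 ± 0.10 on the side of PR39. On the side of S100A11 were RPN2, a subunit of the oligosaccharyltransferase (-0.57 ± 0.11), CYBA, a subunit of the NADPH oxidase (-0.44 ± 0.12), and the glycosyltransferase B3GALNT1 (-0.31 ± 0.07). Without the array of pools 148 and 492, the adjusted p of B3GALNT1 was 0.054. CYBA lost its call in 10 of the 13 fits that left out 1 array, with adjusted p up to 0.159, and ITM2A lost it in 4, with adjusted p up to 0.104. With 1 level per pool and the loop as a block, ITM2A (adjusted p = 0.062) and CYBA (0.118) lost their calls. PAQR8 (-0.37), LMCD1 (0.36) and OCA2 (0.40) also passed the threshold, but their deposited ratios, dye effect included, did not keep 1 sign over the direct arrays. With the dye effect removed each kept 1 sign, at -0.55 to -0.09, 0.23 to 0.49 and 0.07 to 0.59. LMCD1 lost its call in 11 of the fits that left out 1 array and with the loop as a block (0.0728). OCA2 lost it in 2 of those fits, with adjusted p up to 0.0839.

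Among the 16 members of the gene lists, none passed over all probes for the Piau age change (limma). Adjusted over the list alone 4 passed, but lists held 1 to 3 members and 2 of the 4 were alone in theirs, where the p is unadjusted. The same 4 passed when adjusted over the 16 members together. These were the cartilage link protein HAPLN1 (-1.37 ± 0.39, adjusted p over all probes = 0.0508), the myogenic transcription factor MYOD1 (0.60 ± 0.19, 0.0799), the embryonic globin HBE1 (-0.39 ± 0.12, 0.0788) and KLF4 (-0.29 ± 0.10, 0.0907). Over all probes, HAPLN1 passed without the array of pools 3 and 241 (adjusted p = 0.0104), without that of pools 11 and 3 (0.0497), without the crossbred age array of loop 1 (0.0405), without loop 3 (0.00471), with print-block medians removed (0.049) and with arrays centred and scaled (0.026). HBE1 (-0.46, 0.041) and KLF4 (-0.30, 0.0447) passed with arrays centred and scaled too. KLF4 also passed without the array of pools 515 and 386 (0.0163), and MYOD1 without that of pools 11 and 3 (0.035) or the crossbred age array of loop 2 (0.0413). CD4, a coreceptor of T cells at 0.10 (0.202), passed without moderation (0.0482). In the rest of the 25 settings tried for genes, HAPLN1, HBE1, KLF4, MYOD1 and CD4 did not pass over all probes. The slow myosin heavy chain MYH7 was at 0.40 ± 0.29 (adjusted p = 0.526).

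Over all probes, 1786 passed the threshold in Piau, 1079 on the positive and 707 on the negative side, and 234 of them had an absolute value of at least 1. At an unadjusted p under 0.05 there were 4149. The largest values belonged to unnamed probes, with -3.79 for probe 2126 and 2.85 for probe 11166. The count was 1099 from the direct arrays alone and 974 without the dye term.

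In crossbred fetuses, PR39 again led the positive side at 1.40 ± 0.21 (adjusted p = 0.0018), with 3 direct arrays from 1.05 to 1.96, and CAV1 followed at 1.15 ± 0.15 (adjusted p = 0.000809). RPN2 (-0.86 ± 0.13, adjusted p = 0.00168) and S100A11 (-0.84 ± 0.10, adjusted p = 0.000666) led the negative side. The transcription factor JUN was at 0.93 ± 0.20 and the mitochondrial outer membrane protein TSPO at 0.68 ± 0.09. ITM2A was at 0.65 ± 0.11, the leukotriene receptor CYSLTR2 at 0.71 ± 0.13 and TYROBP, a signalling adaptor of myeloid and natural killer cells, at 0.62 ± 0.14. CRSP3 (0.42 ± 0.09) and the ficolin FCN1 (0.35 ± 0.09) lay on the same side.

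The other genes on the negative side were QDPR, the dihydropteridine reductase (-0.67 ± 0.17), SHAS2, a hyaluronan synthase (-0.56 ± 0.10), B3GALNT1 (-0.50 ± 0.08), the integrin subunit ITGB1 (-0.41 ± 0.09) and SAL1, a salivary lipocalin (-0.29 ± 0.06). Of the 16 list members, JUN and TYROBP passed over all probes, adjusted over the list alone (JUN was alone in its list) and adjusted over the 16 together. FCN1 lost its call in 10 fits that left out 1 array and QDPR in 8, with adjusted p up to 0.211 and 0.107, and both lost it with the loop as a block (0.101 and 0.0739). TYROBP lost it in 3, CRSP3 and ITGB1 in 2 each and SAL1 in 1. Without the crossbred age array of loop 2, the adjusted p of JUN was 0.0768.

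In crossbreds 1636 probes passed, 878 positive and 758 negative, with 188 at an absolute value of at least 1 and 4162 at an unadjusted p under 0.05. The largest values were 3.63 for the unnamed probe 7932 and -2.21 for probe 2126. The count was 786 without the dye term and 1024 without moderation. It was 814 without the crossbred age array of loop 1 and 873 without that of loop 2.

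**Figure D1:**
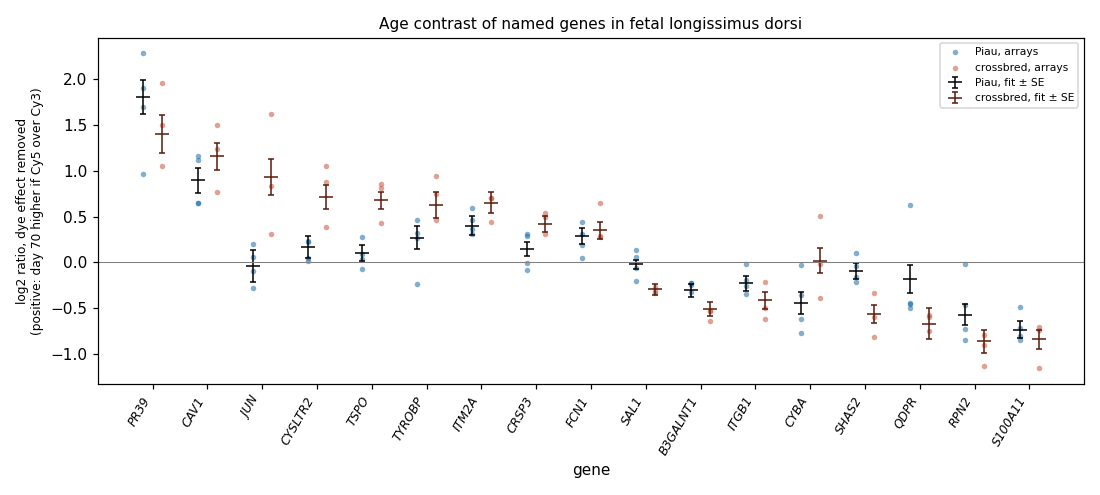
Log2 ratios of the genes taken by the rule for named genes for either age change, with the dye effect removed. Named genes past the threshold that the rule left out are not shown. Points are arrays (4 in Piau, 3 in crossbreds), bars are fitted values with SE, and the vertical axis is positive for day 70 over day 40 if the ratios are Cy5 over Cy3. PR39 and CAV1 lie above 0 and S100A11 below 0 on every array of both breeds.

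The age changes of the breeds were set side by side over all probes, using direct arrays that shared neither an array nor a pool. The correlation across probes was 0.62 (Pearson) and 0.42 (Spearman), and probes are not independent replicates. PR39, CAV1, ITM2A, S100A11, RPN2 and B3GALNT1 passed on the same side in both breeds. Of 771 probes past the threshold in both, 768 lay on the same side, 521 positive and 247 negative, where independent lists would share 45.7 and 25.8. These calls came from 1 fit with a shared spread and shared paths through the loops, so the excess over independent lists includes any error the calls share.

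Whether age acted differently in the breeds was tested by the interaction. No named gene passed over all probes (limma). Of all 20736 probes 0.265% passed, a share at which few or no named probes would be expected. An unadjusted p under 0.05 was found for 16 of the 178 named probes and for 2363 of all probes. Among the named genes the smallest p belonged to TSPO, at -0.57 ± 0.11 (adjusted p = 0.0548). Its age change was 0.10 in Piau and 0.68 in crossbreds. OCA2, a melanosome protein, was at 0.57 ± 0.12 (adjusted p = 0.0666), JUN at -0.97 ± 0.23 (0.106), SHAS2 at 0.47 ± 0.12 (0.122) and SAL1 at 0.27 ± 0.07 (0.133). None of these 5 passed, but TSPO and SHAS2 did without the array of pools 3 and 241 (adjusted p = 0.0264 and 0.0304), TSPO without that of pools 308 and 11 (0.0373), and OCA2 without that of pools 241 and 308 (0.043). TSPO (0.0262) and SHAS2 (0.0268) also passed without loop 3, and TSPO (0.0283) and OCA2 (0.0383) with arrays treated as independent. HAPLN1, at -1.20 ± 0.52 (adjusted p = 0.401), was at -2.13 without loop 3 and passed there (0.0242). In the rest of the 25 settings tried for genes, none of these genes passed over all probes. Of the list members, JUN (alone in its list, so unadjusted) and KLF4 passed adjusted over the list alone, and JUN passed adjusted over the 16 members together (0.021).

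Over all probes 55 passed for the interaction, 33 positive and 22 negative, led by the unnamed probes 7270 (1.48 ± 0.20) and 12430 (1.40 ± 0.12), and on the other side 5652 (-1.28 ± 0.23) and 10959 (-1.22 ± 0.18). The count was 1 with 1 level per pool and 1 from the direct arrays alone, and it ran from 5 to 143 over the fits that left out 1 array, moving by over 1.5 times in 9 of 13.

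The breeds were compared at day 40 of gestation. JUN (probe 15941), an immediate early transcription factor, differed most among the named genes, at 2.26 ± 0.20 (adjusted p = 3.51e-05), with 3 direct arrays from 2.03 to 2.43. KLF4 (probe 4707), a transcription factor, was at 0.94 ± 0.11 (adjusted p = 0.000132) and TSPO (probe 1252) at 0.83 ± 0.09 (adjusted p = 0.000117). On the opposite side, RPN2 (probe 15942) was at -1.23 ± 0.13 (adjusted p = 7.34e-05) and MYOD1 (probe 9028) at -1.08 ± 0.21 (adjusted p = 0.00373). Piau and crossbred RNA had been extracted by different methods, so breed and extraction cannot be told apart here or at day 70.

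Further genes on the side of JUN were the addressin MADCAM1 (0.70 ± 0.15), the phosphatase scaffold PPP2R1A (0.67 ± 0.07) and the membrane progestin receptor PAQR8 (0.53 ± 0.09). The membrane metalloproteinase MMP14 (0.30 ± 0.08), the lysosomal protein LAMP1 (0.29 ± 0.09) and CRSP3 (0.28 ± 0.09) lay on that side too. On the side of RPN2 were SHAS2 (-0.90 ± 0.10), QDPR (-0.64 ± 0.17), B3GALNT1 (-0.59 ± 0.07) and NTAN1 (-0.34 ± 0.09). Of the 16 list members, JUN, KLF4, MYOD1 and MMP14 passed over all probes, adjusted over the list alone (all but KLF4 were alone in theirs) and adjusted over the 16 together. HAPLN1 did not pass at 0.82 ± 0.43 (adjusted p = 0.231), but it did at 1.42 without the array of pools 3 and 241 (0.0273) and at 1.70 without loop 3 (0.00501). It passed in no other of the 25 settings tried for genes. LAMP1 lost its call in 10 fits that left out 1 array and CRSP3 in 7, with adjusted p up to 0.159 and 0.157, MMP14 and QDPR in 2 each, and NTAN1 in 1. With the loop as a block, CRSP3 lost its call (adjusted p = 0.0563).

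At day 40, 4100 probes passed, 19.8% of those tested, 2122 positive and 1978 negative. Of these, 269 had an absolute value of at least 1, and 6368 probes had an unadjusted p under 0.05. The largest values were 3.27 for the unnamed probe 14276 and -3.00 for probe 13573. The count was 2280 without the dye term. Of the 178 named probes 15 passed, a lower share than over all probes.

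At day 70, JUN again had the largest difference between the breeds among the named genes past the threshold, 1.29 ± 0.20 (adjusted p = 0.000889), with 3 direct arrays from 0.55 to 1.76. PPP2R1A was at 0.60 ± 0.07 (adjusted p = 0.000129), KLF4 at 0.57 ± 0.11 (adjusted p = 0.00324) and PGK2, the testis form of phosphoglycerate kinase, at 0.79 ± 0.18 (adjusted p = 0.0104). RPN2 lay at -0.94 ± 0.13 (adjusted p = 0.00041) with 3 direct arrays between -1.03 and -0.99, and MYOD1 at -0.88 ± 0.21 (adjusted p = 0.0135).

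The growth factor FGF9 (0.54 ± 0.13), S100A11 (0.38 ± 0.10), OCA2 (0.34 ± 0.10) and ITGB1 (0.32 ± 0.09) lay on the side of JUN. So did MMP14 (0.26 ± 0.08), the cation transporter SLC22A2 (0.26 ± 0.08) and SAL1 (0.21 ± 0.06). CYBA (-0.53 ± 0.13), SHAS2 (-0.43 ± 0.10) and B3GALNT1 (-0.39 ± 0.07) lay on the side of RPN2. MAOA (-0.29) passed too, but its deposited ratios, dye effect included, did not keep 1 sign. With the dye effect removed, its 3 direct arrays ran from -0.48 to -0.18. Of the 16 list members, JUN, KLF4, MYOD1 and MMP14 passed over all probes and adjusted over the 16 together. The desmosomal cadherin DSG1 (-0.20 ± 0.09), alone in its list, had an unadjusted p of 0.0497 and did not pass over the 16 (0.159). Without the array of pools 308 and 11, the adjusted p of MYOD1 was 0.073. SLC22A2 lost its call in 10 fits that left out 1 array, MMP14 in 7 and OCA2 in 6, with CYBA, ITGB1 and SAL1 in 2 each and FGF9 and S100A11 in 1 each. MAOA lost it in 11, with adjusted p up to 0.2. With the loop as a block, MMP14 (0.0535), CYBA (0.056), SAL1 (0.0721), SLC22A2 (0.0777), OCA2 (0.0817) and MAOA (0.132) lost their calls.

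At day 70, 3462 probes passed, 16.7% of those tested, 1776 positive and 1686 negative, with 239 at an absolute value of at least 1 and 5734 at an unadjusted p under 0.05. The largest values were 2.94 for the unnamed probe 12066 and -2.31 for probe 20724. The count was 1937 without the dye term. Of the 178 named probes 17 passed, a lower share than over all probes.

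**Figure D2:**
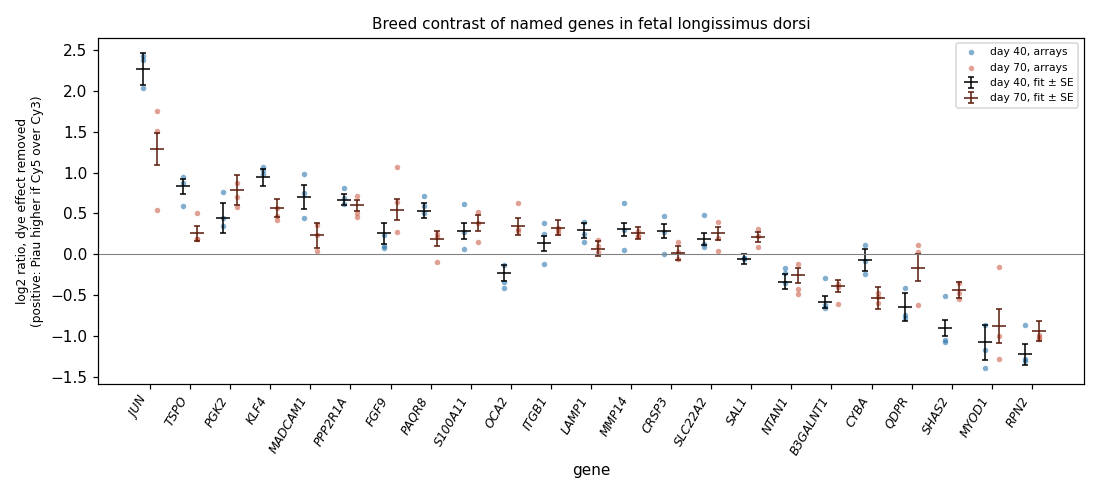
Log2 ratios of the genes taken by the rule for named genes for either breed difference, with the dye effect removed. MAOA, which passed the threshold but was left out by the rule, is not shown. Points are arrays (3 at each age), bars are fitted values with SE, and the vertical axis is positive for Piau over crossbred if the ratios are Cy5 over Cy3. JUN and KLF4 lie above 0 and RPN2, SHAS2 and MYOD1 below 0 on every array.

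The breed differences at the 2 ages correlated across probes at 0.68 (Pearson) and 0.62 (Spearman), from direct arrays that shared neither an array nor a pool. JUN, KLF4, PPP2R1A, MMP14, RPN2, MYOD1, SHAS2 and B3GALNT1 passed on the same side at both ages. Of 2323 probes past the threshold at both ages, 2321 lay on the same side, 1215 positive and 1106 negative, where independent lists would share 181.7 and 160.8. The calls again came from 1 fit, and the excess includes any error they share. The extraction method differed between the breeds in the same way at both ages, so the agreement cannot be credited to breed alone.

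Averaged over breeds, 2565 probes passed for the age change, 1473 positive and 1092 negative, and 20 of them were named. Averaged over ages, 5143 probes passed for the breed difference, 2635 positive and 2508 negative, and 24 were named. These 24 are a smaller share of the 178 named probes than the 5143 are of all 20736. The named genes with the smallest adjusted p for the average breed difference included PPP2R1A (0.63) and JUN (1.78) on one side and RPN2 (-1.08) on the other.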

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

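The array of pools 148 and 492 stood apart from the 3 other Piau age arrays for B3GALNT1, at -0.32 against -0.24 to -0.23. It was 1 of 12 sets of 4 arrays tested, and chance flags about 1 in 20 such sets. The age changes of the breeds differed for the 55 probes past the threshold of the interaction, none of them named. After the additive breed and age effects were subtracted, a step chosen after the result was seen, 1 of 100 splits of the pools within ages, the real one, gave as many. The highest other gave 50, from a split that exchanged the breeds of all but 2 pools. With exchanges kept within loops, an addition made after the result was seen, 3 of 64 splits gave as many. Both shares are under 0.05 as counted. Within loops, however, each split has a mirror that exchanges the breeds of all pools in the loops and carries nearly the same contrast. With a split and its mirror counted as 1, the share within loops would not be under 0.05. The split that exchanged the day 40 pools of loop 3 gave 70, more than the real one. Only 1 probe passed with the loop as a block and 0 without loop 1. In the other direction, 192 passed without loop 3 and 143 without its array of pools 3 and 241. The 55 thus rest on the choice of fit and of arrays, and whether they are chance is left open.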

How the results depend on the processing

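Removing print-block medians, leaving out single arrays and, for named genes, the settings of dye, scaling, independence and moderation were chosen after the data were seen. Of 210 recomputed counts, 146 stayed within 1.5 times. The 210 include turning the sign of all arrays, which cannot change a count, and centring arrays whose medians were already near 0. They also include 1 value per named gene, which rests on far fewer tests. The share is therefore no measure of robustness by itself. Without the dye term the counts were 974 (age change in Piau), 786 (age change in crossbreds), 2280 and 1937 (breed difference at days 40 and 70), 18 (interaction), 1331 (average age change) and 3005 (average breed difference). In the same order, an adjusted p under 0.01 gave 847, 674, 2227, 1837, 2, 1285 and 3136. With 1 value per named gene, and so far fewer tests, they were 8, 17, 12, 12, 2, 18 and 16, and the 2 of the interaction were OCA2 and TSPO. Requiring at least 1.5-fold left 689, 649, 1324 and 1160 for the 4 comparisons, and 608 and 1141 for the averages. The direct arrays alone gave 1099 for Piau age, and no moderation gave 1024 for crossbred age. The interaction count was 198 with arrays treated as independent, 1 with 1 level per pool, 1 from direct arrays alone, 29 after centring and scaling (75.9% positive against 60%), 7 without moderation and 233 at an adjusted p under 0.10. Leaving out a loop or an array gave 699 to 1928 for Piau age, 411 to 1678 for crossbred age, 1791 to 4220 and 1519 to 3663 for the breed differences, 0 to 192 for the interaction, and 1099 to 2544 and 3025 to 5418 for the averages. The cause was not tested, and some counts rose with fewer arrays. Of 58 gene calls in the 4 comparisons, 31 were kept in every fit that left out 1 array, and 18 in all 25 settings tried for genes, which leave out the stricter thresholds. The fewest were kept without loop 1 and without loop 2, 25 each, then 36 from the direct arrays alone, and 39 each without loop 3 and without the dye term. Without moderation 45 were kept, after scaling 48, and 44 to 54 in the fits that left out 1 array. Those 18 were PR39, CAV1 and S100A11 for both age changes, RPN2 for crossbred age, and JUN, RPN2 and PPP2R1A at both days with KLF4, TSPO, SHAS2, PAQR8 and B3GALNT1 at day 40. Of 3300 recomputed gene values, 285 fell below the threshold, 23 passed it only there, and 0 changed sign with a call on either side. Another 143 changed sign with no call on either side, and the other 2849 kept their direction and side of the threshold. Turning the sign of all arrays kept every count, as it must with two-sided tests. Probes measured on all arrays were all probes, so that alternative changed nothing. The gene list tests and their alternatives were not run. The loops tie 1 pool of each group together: with the loop as a replicate block the counts were 1477, 1103, 3409 and 2874 for the 4 comparisons and 1 for the interaction, and 46 of the 58 gene calls were kept. Signal over background was unknown.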

Other observations

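The tests of print position, of myeloid genes and of HBE1 were chosen after the results were seen. The average age change over breeds called genes that passed in neither breed alone. The folate receptor FOLR1 was at 0.57 (adjusted p = 0.0174 from limma), against 0.56 in Piau and 0.59 in crossbreds. The calcium channel subunit CACNB4 was at 0.26 (adjusted p = 0.0195) and the complement regulator CD46 at -0.23 (adjusted p = 0.0481). For the average breed difference, the aminotransferase GOT1 was at -0.19 (adjusted p = 0.0289). These 4 genes fall outside the rule for named genes and were chosen after their values were seen.

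Breed differences, averaged over ages, covered 24.8% of all probes, led by JUN and RPN2 among the named. Of the 178 named probes 24 passed, a lower share, so the named genes do not stand for the array as a whole. Position on the slide was tested by removing each print block's median, after which 5388 probes passed against 5143. Shifts of whole blocks left in the deposited ratios therefore do not account for the breed differences. If the LOESS step worked block by block, such shifts were already gone and the test could not find them. Effects of position within a block were not tested. The deposited ratios were already centred, so an offset common to all probes could not be tested. Also open is the extraction method: 0 pools of a breed were extracted by the other breed's method, so method and breed cannot be told apart. The differences in JUN and KLF4 may belong to either. Handling of the tissue before extraction, which can induce immediate early genes such as JUN, was not tested. JUN was the only named member of the list of stress and immediate early genes, and KLF4 had been listed with the adipocyte genes.

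PR39 had the largest average age change among named genes past the threshold, at 1.60, and a candidate explanation is a change in myeloid cells, which make this peptide. The median of 7 other genes known from myeloid cells was 0.0287, above 80.7% of 10000 random lists of named probes. TYROBP (0.45) and FCN1 (0.32) passed on the side of PR39, while NPG4 (0.16), PGLYRP1 (0.03), SIGLEC1 (0.01), CCR2 (-0.03) and CYBA (-0.21) did not pass. The test leaves the explanation open, and a change in PR39 within other cells was not tested.

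The sign of the ratios could be read from HBE1, an embryonic globin that would likely be lower at day 70. Its average age change was -0.31 ± 0.10, the side that Cy5 over Cy3 would make lower, but the adjusted p was 0.0741. Its Piau age change passed with arrays centred and scaled (-0.46, adjusted p = 0.041), the only one of the 25 settings tried for genes in which it did. The sign therefore stays open.

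Other splits of the pools into groups of the same sizes were counted, at first over all pools and then, as an addition made after the results were seen, with exchanges kept within loops, since each loop ties 1 pool of each group together. For the average age change, the real split alone gave as many as 2565 probes, among 100 splits over all pools (highest other 1126) and among 64 within loops (highest other 320). For the average breed difference, the real split alone gave as many as 5143, among 100 (highest other 847) and among 64 (highest other 5006). The split with 5006 exchanged the breeds of all pools in the loops, so it carries the same contrast with the pools outside the loops misplaced. Chance can be excluded at the level of 0.05 for these 2. For the age change in Piau and the breed differences at days 40 and 70 the splits within loops are 8 each, and for the age change in crossbreds they are 4, too few for a share under 0.05. The real values were 1786, 4100, 3462 and 1636, against a highest other within loops of 0, 2760, 2143 and 0. Over all pools, 35 splits gave at most 258, 2760 and 2143 for the first 3, and 10 splits gave at most 0 for the crossbreds, but they break the loops. The 2760 and 2143 again came from exchanging the breeds of all pools in the loops.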
